A study of Mus musculus with 12 samples.

How the data were processed

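Left ventricle RNA of 12 mice was measured by sequencing of polyadenylated RNA, 1 library per mouse and 4 per group. The deposited values are raw read counts per gene, 1 column per library, as the authors made them from reads trimmed with fastp and placed on genome build GRCm39 (mm39). The version of fastp, the aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. The values were whole numbers with a different total in each library, 13352604 to 19236721, so they were taken as counts with no normalization. The labels name the source as left ventricle and the cell type as cardiomyocytes, and the tissue was treated as whole left ventricle, with markers of other cell types read only as transcript levels. The labels give 1 batch for all 12 libraries. The table held 56748 genes under symbols, of which 882 were repeats of another symbol with 0.0011% of all counts and 2693 carried only an Ensembl name. No pair of libraries within a group was a duplicate by a check on genes with at least 20 counts, and pairs between groups were not checked. All numeric columns belonged to a sample.

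Differences were tested in edgeR 4.0.16 under R 4.3.3 with the quasi-likelihood test, robust fitting, TMM factors and the filterByExpr filter by group, which left 15742 genes. The model had 1 term per group over all 12 libraries and 9 residual degrees of freedom. The 3 contrasts were infarction against sham under control vector, Irx3 vector against control vector after infarction, and Irx3 vector with infarction against sham. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 fold changes are the size of the fold change over the square root of the F statistic. Those of slopes on GC content and of list medians are taken over genes, so they do not measure the spread among mice. Normalised read counts are CPM from edgeR with the TMM factors, and log2 values of single libraries use a prior count of 1. For a gene with 0 counts in a group the ratio is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it carries a 95% counting interval. The two-sided exact permutation test was used for Irx3 and for the share of mitochondrial counts, with 70 assignments and a smallest p of 0.029.

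Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with adjustment over 47 lists and 3 contrasts together (141 tests). The lists covered matrix, signalling, inflammation, muscle, metabolism, vessels, conduction and markers of the cell types of the ventricle. Members called were counted over all genes tested and adjusted over the list alone. Groups, contrasts, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule took Irx3 and the other Iroquois genes, the 8 largest rises and falls per contrast among called genes with a mean log2 CPM of at least 2 and groups fully apart, which chance gives with probability 0.029, the members of each list with the smallest p, and the 5 genes per direction with the largest opposite changes. A part of the genes the rule gave is named.

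Because fold changes with Irx3 vector followed GC content, a correction was added that was chosen after seeing the data. For each library a natural spline with 6 degrees of freedom was fitted to the deviation of log2 CPM against GC content over genes with a mean of at least 2, in 3 rounds that left out residuals beyond 2.5 median absolute deviations, and entered as an offset. GC content came from GENCODE M21 transcripts on GRCm38, matched by symbol for 15182 genes, 96.4% of those tested, since no annotation on GRCm39 was among the sources used here. From that annotation names and base composition were used, not positions. A further pair of alternatives was added after seeing the data, leaving out replicate 4 of infarction with control vector and replicate 4 with Irx3 vector together, without and with the GC correction.

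Alternatives named in advance were RLE factors of edgeR, upper-quartile factors, the DESeq2 1.42.0 Wald test, no filter and a filter of a CPM of 1 in 4 libraries. Others named in advance were only the 2 groups compared, mitochondrial genes removed, replicate number as a block and glmTreat against a fold change of 1.5. So were each library left out in turn, camera with an estimated correlation and fry. The replicate numbers were checked for pairing by the correlation of residuals between libraries of the same number. Correlation from the shared control vector infarction libraries was measured in 20 simulations and by dividing those libraries between the contrasts. Each count was repeated over all 35 splits of its 8 libraries.

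The steps were tested on simulated data, with 200 changed genes at the mean levels and gene-wise spread of these libraries. At a 4-fold change 89.4%, 87.9% and 87.9% of genes were recovered in the 3 contrasts, at a 2-fold change 49.3%, 41.8% and 50.7%, and at a 1.5-fold change 4.48%, 11.9% and 13.4%, with 9, 3 and 5 unchanged genes called. With a GC trend added, 4826 unchanged genes were called uncorrected and 4 after the correction, which recovered 84.8% at a 4-fold change and 38.8% at a 2-fold change. That trend was a smooth function of the same GC values that the correction fits, alike in the 4 Irx3 vector libraries. The simulation therefore does not test GC effects that scatter around such a curve, or errors in the GC values. At this depth, with 4 libraries per group and 200 genes changed, most 1.5-fold changes went undetected in the simulation. The adjusted p is stricter when few genes change, so these shares do not measure recovery in the real contrasts, where many more were called. With the GC trend uncorrected, 43.3% of 1.5-fold changes were recovered. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Splice forms, sequence variants and vector reads were not analysed here. Results for some genes are not reported here.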

Results

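Polyadenylated RNA was sequenced from the left ventricle of 12 C57BL/6J mice in 3 groups of 4. All mice received an adeno-associated virus of serotype AAV9, a vector with a preference for heart muscle, as a control vector or as a vector for Irx3, which encodes a homeobox transcription factor of the Iroquois family. The left anterior descending coronary artery was tied to cause myocardial infarction, or sham surgery was done, and tissue was taken 14 days later. The groups were control vector with sham surgery, control vector with infarction, and Irx3 vector with infarction. No group had Irx3 vector with sham surgery, so the vector was compared only in infarcted hearts. Total counts per library ran from 15966982 to 18441830 in the sham group. They ran from 16081360 to 18738571 after infarction with control vector and from 13352604 to 19236721 after infarction with Irx3 vector. The first principal component of the 1000 most variable genes held 67.7% of their variance and the second held 17.8%.

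Irx3 transcript was measured first, to see whether the vector raised its target. Its normalised read count was 24.5 CPM ± 2.65 (SD, n = 4) in sham hearts, 23.1 ± 6.89 (SD, n = 4) after infarction with control vector and 393 ± 111 (SD, n = 4) after infarction with Irx3 vector. Irx3 vector raised Irx3 17.1-fold over control vector after infarction (log2 fold change 4.09, SE 0.25, edgeR adjusted p = 1.48e-06), and the lowest library with the vector held 5232 counts against 593 in the highest with control vector. A two-sided exact permutation test of CPM gave p = 0.029, the smallest that 4 against 4 allows. Infarction with control vector left Irx3 at a log2 fold change of -0.09 (SE 0.23, edgeR adjusted p = 0.779). The counts per gene do not separate transcript of the vector from that of the mouse gene. Among the other Iroquois genes, Irx4, a marker of ventricular muscle, fell by 1.00 on the log2 scale after infarction (SE 0.24, edgeR adjusted p = 0.00445). It was higher by 1.40 with Irx3 vector than with control vector (SE 0.24, edgeR adjusted p = 0.000527). Irx1 fell by 1.58 after infarction (SE 0.47, edgeR adjusted p = 0.0133). Both infarction calls ended when a fold change above 1.5 was required (adjusted p = 0.0507 for Irx1 and 0.0653 for Irx4), and that of Irx1 without the filter on low counts (adjusted p = 0.0656). Irx2 and Irx5 passed in neither comparison. Their log2 fold changes were -0.35 (adjusted p = 0.678) and 0.44 (adjusted p = 0.298) after infarction. With Irx3 vector they were 0.64 (adjusted p = 0.416) and 0.15 (adjusted p = 0.73). Without sham replicate 2, Irx5 passed after infarction at 0.84 (adjusted p = 0.042).

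**Figure D1:**
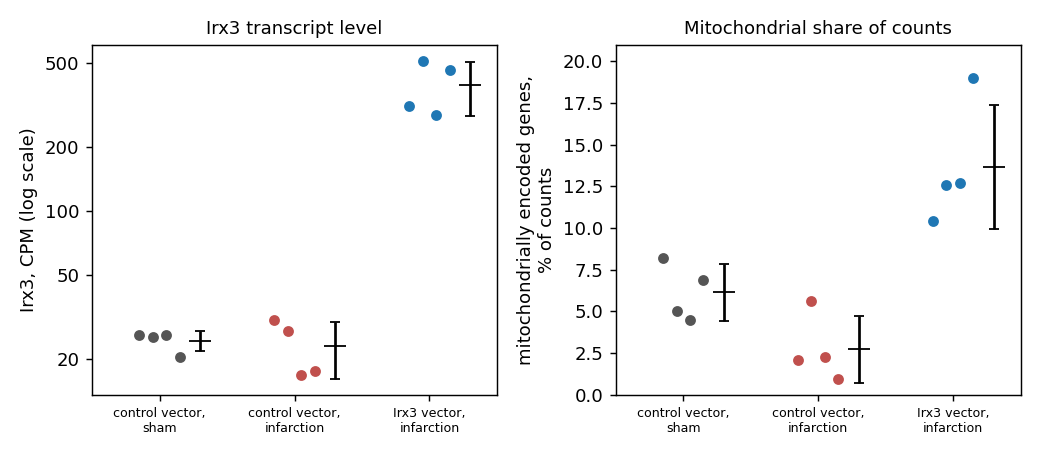
Irx3 transcript in CPM on a log axis and the share of all counts from mitochondrially encoded genes in percent, each point 1 library, with bars for the mean and SD of the 4 libraries per group. The Irx3 vector libraries lay between 285 and 513 CPM of Irx3, above the highest of the other libraries at 30.5, and between 10.4% and 19% mitochondrial counts, above the highest of the others at 8.22%.

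The first comparison asked what infarction changed under control vector. Genes of the extracellular matrix and markers of fibroblasts were higher. Of 40 genes for fibrillar collagens and other matrix proteins, 39 rose and none fell. The matrix list had 39 rises adjusted over the list alone and a median log2 fold change of 4.00 (camera adjusted p = 4.1e-30, and adjusted p = 0.552 with an estimated correlation). Comp, a matrix protein of cartilage and tendon, went from 2.02 CPM ± 0.71 (SD, n = 4) to 3010 ± 2430 (SD, n = 4), a log2 fold change of 10.53 (SE 1.26, edgeR adjusted p = 5.34e-05). Postn, which encodes the activated fibroblast protein periostin, rose from 16.8 ± 4.3 to 985 ± 207 CPM (log2 fold change 5.88, SE 0.44). The collagen genes Col8a1 and Col12a1 rose by log2 fold changes of 4.57 (SE 0.35) and 6.41 (SE 0.51). All 9 matrifibrocyte markers, genes of fibroblasts in a mature scar, rose, 9 of them adjusted over the list alone. Their median was 6.73 (camera adjusted p = 2.45e-08, and adjusted p = 0.552 with an estimated correlation). Among them were Angptl7 at 6.73 (SE 0.68), Cilp2 at 8.04 (SE 0.76) and Fmod at 8.87 (SE 0.81). Comp stood at 9.74 without replicate 4 of infarction with control vector, and Fmod at 9.54 without sham replicate 4. Of 16 markers of activated fibroblasts 14 rose, Cthrc1 at 9.19 (SE 1.02) being among the 8 largest rises of all. Of 15 markers of resident fibroblasts 13 rose and 1 fell. Adjusted over the list alone these were 14, and 13 with 1, at medians of 4.16 and 1.72. Camera gave adjusted p = 1.27e-14 and 2.07e-06, and adjusted p = 0.552 for both with an estimated correlation.

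Some of the largest rises after infarction started from almost no counts in sham hearts. B4galnt3, which encodes a glycosyltransferase, had 0 counts in the sham group and was at least 210-fold higher after infarction, at a floor of 3 counts over the group. Ighg2b, an immunoglobulin heavy chain gene, also had 0 and was at least 291-fold higher, a call that ended without the filter on low counts (adjusted p = 0.0503). C1qtnf3, Ecrg4 and Col6a5 had 1, 2 and 1 sham counts and ratios of 2950 (95% counting interval 530 to 117000), 1220 (338 to 10100) and 807 (145 to 31900). Without replicate 4 of infarction with control vector, Ighg2b was at least 83.1-fold higher and the ratios of C1qtnf3 and Col6a5 were 1720 and 289. Without sham replicate 4 the ratio of Ecrg4 was 1850. Floors and intervals here and further on cover counting error only.

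Genes of immune cells and of their signals were higher after infarction too. Of 43 interferon response genes 42 rose and none fell, 42 of them adjusted over the list alone. The interferon list had a median log2 fold change of 2.59 (camera adjusted p = 3.16e-22, and adjusted p = 0.552 with an estimated correlation). It held Irf7, a transcription factor that amplifies the interferon response, at 4.05 (SE 0.30) and the ubiquitin-like Isg15 at 3.39 (SE 0.34). Of 42 genes for inflammatory cytokines and chemokines 37 rose and none fell. The cytokine list had 38 rises adjusted over the list alone and a median of 2.90 (camera adjusted p = 1.97e-11, and adjusted p = 0.552 with an estimated correlation), and of 2.03 without replicate 4 of infarction with control vector. All 9 genes of antigen presentation by MHC class II rose, with Cd74, the invariant chain, at 2.43 (SE 0.27). All 18 markers of T and NK cells rose, with the interleukin receptor chain Il2rb at 2.88 (SE 0.31). Of 25 macrophage and monocyte markers 19 rose and 2 fell, with the lipid-sensing receptor Trem2 at 4.71 (SE 0.56). Counts adjusted over the list alone were the same for these 3. Camera gave adjusted p = 9.48e-09, 1.21e-06 and 1.42e-07, and adjusted p = 0.552 for each with an estimated correlation. Cell cycle genes rose in 34 of 38 cases and none fell, with the mitotic kinase Cdk1 at 3.77 (SE 0.41). The cell cycle list had 35 rises adjusted over the list alone and a median of 1.86 (camera adjusted p = 2.41e-12, and adjusted p = 0.552 with an estimated correlation).

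Stress genes of heart muscle were higher, and genes of its metabolism, excitation and contraction were lower. Of 24 genes of the fetal programme and wall stress 18 rose and 1 fell, the same adjusted over the list alone. The fetal programme list had a median of 1.99 (camera adjusted p = 6.6e-09, and adjusted p = 0.437 with an estimated correlation). The natriuretic peptide genes Nppa and Nppb rose by log2 fold changes of 6.14 (SE 0.79) and 4.45 (SE 0.28), Nppa by 7.24 without sham replicate 2. The stress cytokine gene Gdf15 rose from 1.85 ± 0.155 to 138 ± 63.7 CPM. All 35 genes of the TCA cycle and branched-chain amino acid oxidation fell, with Ivd at -1.72 (SE 0.27). So did 38 of 42 genes of fatty acid oxidation, with Mlycd at -1.65 (SE 0.26). The same held for 69 of 79 nuclear genes of oxidative phosphorylation, with Sdha, a subunit of complex II, at -1.51 (SE 0.28). Only 1 gene rose in these 3 lists, in fatty acid oxidation. Adjusted over the list alone the falls were 35, 38 and 72, at medians of -1.28, -1.43 and -1.07. Camera gave adjusted p = 1.05e-13, 4.62e-13 and 2.99e-13, and adjusted p = 0.552, 0.552 and 0.635 with an estimated correlation. Of 13 mitochondrially encoded transcripts 7 fell and none rose, the same adjusted over the list alone. Their median was -1.54 (camera adjusted p = 0.00168, and adjusted p = 0.686 with an estimated correlation), and -2.54 without replicate 2 of infarction with control vector. Of 12 cardiomyocyte markers 9 fell and 1 rose, the same adjusted over the list alone (median -1.17, camera adjusted p = 0.0112, and adjusted p = 0.677 with an estimated correlation). Of 33 genes for calcium handling and excitation 24 fell and 2 rose, with the calcium release channel gene Ryr2 at -1.49 (SE 0.26). Of 27 contractile genes 16 fell, with the myosin heavy chain gene Myh6 at -1.48 (SE 0.37). Adjusted over the list alone the falls were 24 and 19. Camera gave adjusted p = 3.89e-09 and 0.000168, and adjusted p = 0.552 and 0.68 with an estimated correlation.

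The potassium channel subunit gene Kcnv2 had the largest fall of the named genes after infarction, a log2 fold change of -4.48 (SE 0.37), from 30.7 ± 4.79 to 1.38 ± 0.659 CPM. Pfkfb1, a regulator of glycolysis, stood at -3.26 (SE 0.51). The chloride channel gene Clcn1 stood at -3.67 (SE 0.51) and the sodium channel subunit gene Scn4b at -3.18 (SE 0.64). Acsm5, Klhl33 and Sec14l5 stood at -3.60, -3.79 and -3.02. Without replicate 2 of infarction with control vector, Pfkfb1 stood at -4.13, Scn4b at -3.89 and Acsm5 at -4.66. In all, edgeR called 7662 of 15742 genes after infarction, 4141 higher and 3521 lower, and 28 of 47 lists passed with the preset correlation of 0.01. With camera and an estimated correlation 0 lists passed in each of the 3 comparisons, at an unadjusted p under 0.05 6, 1 and 0 did, and fry called 33, 17 and 32. After correction for the GC content of transcripts, 7274 of the 7430 calls with a known GC content kept their direction and none turned.

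**Figure D2:**
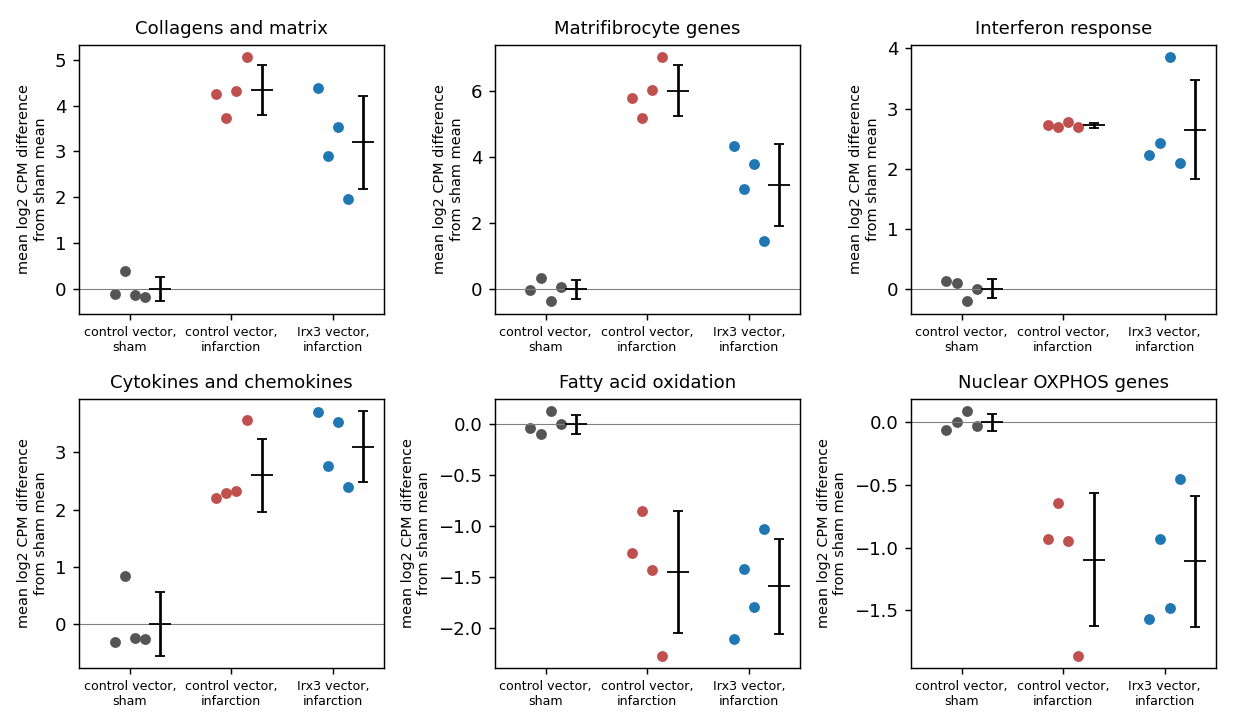
Per-library scores of 6 gene lists, as the mean log2 difference of the members from the sham mean, each point 1 library and bars the mean and SD of the 4 libraries per group. The matrix score was 3.73 to 5.06 after infarction with control vector and 1.97 to 4.38 with Irx3 vector.

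The second comparison asked what Irx3 vector changed in infarcted hearts, against control vector after infarction. Mitochondrially encoded transcripts had the highest median of the 47 lists. All 13 listed genes rose, 13 of them adjusted over the list alone. Their median log2 fold change was 3.02 (camera adjusted p = 6.09e-07, and adjusted p = 0.552 with an estimated correlation). All mitochondrially encoded genes together held 13.7% ± 3.71 (SD, n = 4) of all counts with Irx3 vector, 2.72% ± 2.03 (SD, n = 4) with control vector and 6.15% ± 1.72 (SD, n = 4) in sham hearts. The exact permutation p of that share was 0.029 for Irx3 vector against either other group. The complex I gene mt-Nd4 rose by 2.38 (SE 0.37), mt-Nd6, from the other strand, by 5.17 (SE 0.67) and mt-Nd3 by 5.30 (SE 0.75). Mitochondrial tRNA genes were also among the 8 largest rises. In the control vector group mt-Te had 1 count, which gave a ratio of 5150 (95% counting interval 925 to 204000). There mt-Tl1 had 0 counts and was at least 480-fold higher, at a floor of 3 counts over the group. Without replicate 2 of infarction with control vector, mt-Tl2 went from 5.84 to 9.30, mt-Atp8 from 5.14 to 7.82 and mt-Tw from 5.02 to 8.87. The remaining libraries of that group held at most 0.171 CPM of these genes, so the higher values rest on almost no counts. Without that replicate 2, mt-Nd6 stood at 6.19, mt-Nd3 at 6.53 and the list median at 4.18, and without replicate 4 with Irx3 vector mt-Atp8 stood at 4.30. Nuclear genes of oxidative phosphorylation did not pass as a list, with 9 of 79 higher and 9 lower, or 0 and 3 adjusted over the list alone. Their median was -0.12 (camera adjusted p = 0.474).

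Fold changes between the infarcted groups followed the GC content of transcripts. The Spearman correlation across genes of log2 fold change and GC content was -0.65 for Irx3 vector against control vector, -0.44 for Irx3 vector against sham and 0.04 for infarction. Genes are not independent replicates, so no p is given. Among the 1519 genes of lowest GC content, 22.1% to 41.4%, 1167 were called higher with Irx3 vector at a median log2 fold change of 1.14. Among the 1519 of highest GC content, 57.8% to 78.3%, 861 were called lower at a median of -0.66. A correction fitted to each library, chosen after seeing the data, brought those medians to 0.09 and -0.01. After it the 13 mitochondrially encoded genes had 10 rises at a median of 2.02 (camera adjusted p = 5.89e-08, and adjusted p = 0.494 with an estimated correlation). There mt-Nd4 stood at 0.99 (adjusted p = 0.0183) and Irx3 itself at 4.70 (adjusted p = 1.98e-06). Without replicate 4 of both infarcted groups as well, chosen after seeing the data, the list still passed at a median of 1.15 and mt-Atp8 did not pass (2.71, adjusted p = 0.0536). Values after this correction are given as GC-corrected from here on.

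**Figure D3:**
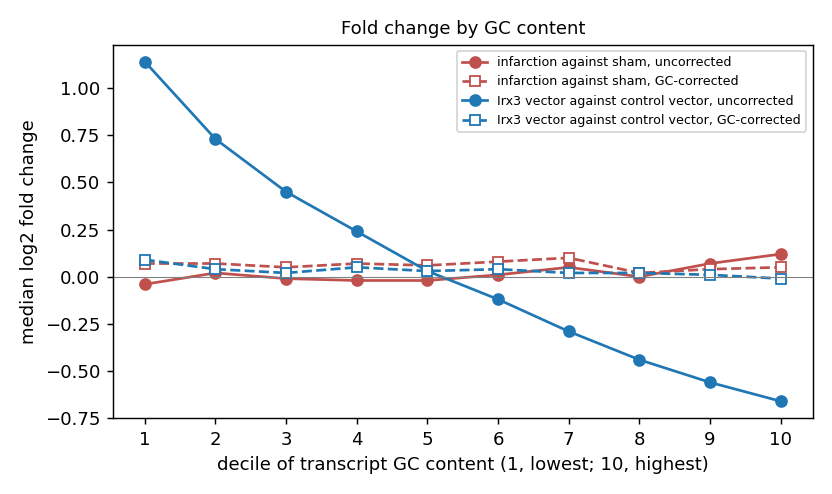
Median log2 fold change of tested genes in 10 classes of transcript GC content, for infarction and for Irx3 vector after infarction, before and after the GC correction. For Irx3 vector the uncorrected median went from 1.14 in the lowest class to -0.66 in the highest, and from 0.09 to -0.01 once corrected.

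Most matrifibrocyte markers and some matrix genes were called lower with Irx3 vector than with control vector. Of 9 matrifibrocyte markers 8 fell and none rose, the same adjusted over the list alone. The matrifibrocyte list had a median of -2.33 (camera adjusted p = 0.000437, and adjusted p = 0.552 with an estimated correlation). GC-corrected it had 6 falls and a median of -1.91. Comp fell by 3.41 (SE 0.91, GC-corrected -2.65) to 282 CPM ± 290 (SD, n = 4). Chad, a cartilage matrix protein gene, fell by 3.33 (SE 0.53, GC-corrected -2.69), Cilp2 by 3.45 (SE 0.53, GC-corrected -2.78) and Fmod by 2.33 (SE 0.57, GC-corrected -1.91). Without replicate 4 of infarction with control vector, Chad stood at -2.54 and Comp at -2.66. Without replicate 1 with Irx3 vector, Comp stood at -4.27, Cilp2 at -4.13 and the matrifibrocyte median at -3.19. Of the 40 matrix genes 16 fell and none rose. The matrix list had 13 falls adjusted over the list alone and a median of -0.98 (camera adjusted p = 0.00064, and adjusted p = 0.772 with an estimated correlation). GC-corrected, 6 fell and 1 rose at a median of -0.64. Uncorrected, fry, which does not compare with other genes, gave no call for this list (adjusted p = 0.0836). The resident fibroblast markers fell in 8 of 15 cases, the same adjusted over the list alone. Their median was -0.84 (camera adjusted p = 0.0128, and adjusted p = 0.68 with an estimated correlation), and -0.59 GC-corrected. Examples were Pi16 at -1.77 (SE 0.32, GC-corrected -1.27) and the transcription factor gene Tcf21 at -1.42 (SE 0.26, GC-corrected -1.33). The 16 activated fibroblast markers did not pass as a list, with 1 higher and 3 lower, or 0 and 3 adjusted over the list alone. Their median was -0.13 (camera adjusted p = 0.426), and -0.51 GC-corrected (camera adjusted p = 0.0905). The matrix and resident fibroblast medians became -0.56 and -0.33 without replicate 4 of infarction with control vector. That library had the highest matrix score, 5.06, and the lowest mitochondrial share, 0.926%. Without that library and replicate 4 with Irx3 vector, the resident fibroblast list no longer passed (median -0.27, adjusted p = 0.104). With the GC correction as well, neither did the matrix list (median -0.13, adjusted p = 0.203), Comp (-1.65, adjusted p = 0.0508) or Fmod (-1.36, adjusted p = 0.0516).

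Lists for TGF-beta signalling, wall stress, cell division, ribosomal proteins and endothelium were lower as well. Of 32 genes of TGF-beta signalling 17 fell and 4 rose, the same adjusted over the list alone. Their median was -0.39 (camera adjusted p = 0.00064, and adjusted p = 0.677 with an estimated correlation). It was -0.42 GC-corrected and -0.25 without replicate 4 of infarction with control vector. The ligand gene Tgfb2 rose by 1.35 (SE 0.17, GC-corrected 1.13). Of 24 genes of the fetal programme and wall stress 13 fell and none rose, the same adjusted over the list alone. The fetal programme list had a median of -0.70 (camera adjusted p = 9.56e-05, and adjusted p = 0.552 with an estimated correlation), and of -0.69 GC-corrected. Its member Gdf15 stood at -3.01 (SE 0.33, GC-corrected -2.31). Cell cycle genes fell in 16 of 38 cases and rose in 2, the same adjusted over the list alone. Their median was -0.60 (camera adjusted p = 0.00409, and adjusted p = 0.75 with an estimated correlation). It was -0.70 GC-corrected and -0.39 without replicate 2 with Irx3 vector. Examples were Mcm2, part of the replicative helicase, at -1.29 (SE 0.17, GC-corrected -1.04) and Cdc20, an activator of the anaphase-promoting complex, at -1.98 (SE 0.28, GC-corrected -1.44). Cytosolic ribosomal protein genes fell in 28 of 46 cases and rose in 1, the same adjusted over the list alone. The ribosomal protein list had a median of -0.63 (camera adjusted p = 1.51e-07, and adjusted p = 0.552 with an estimated correlation), and of -0.46 GC-corrected. Examples were Rps28 at -1.92 (SE 0.25, GC-corrected -1.92) and Rpl38 at -1.52 (SE 0.18, GC-corrected -0.86). Endothelial markers fell in 11 of 15 cases and rose in 3, the same adjusted over the list alone. The endothelial list had a median of -0.75 (camera adjusted p = 0.00685, and adjusted p = 0.552 with an estimated correlation), and of -0.39 GC-corrected. Examples were Rgcc at -1.53 (SE 0.19, GC-corrected -1.11) and the adhesion molecule gene Esam at -0.86 (SE 0.13, GC-corrected -0.47).

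**Figure D4:**
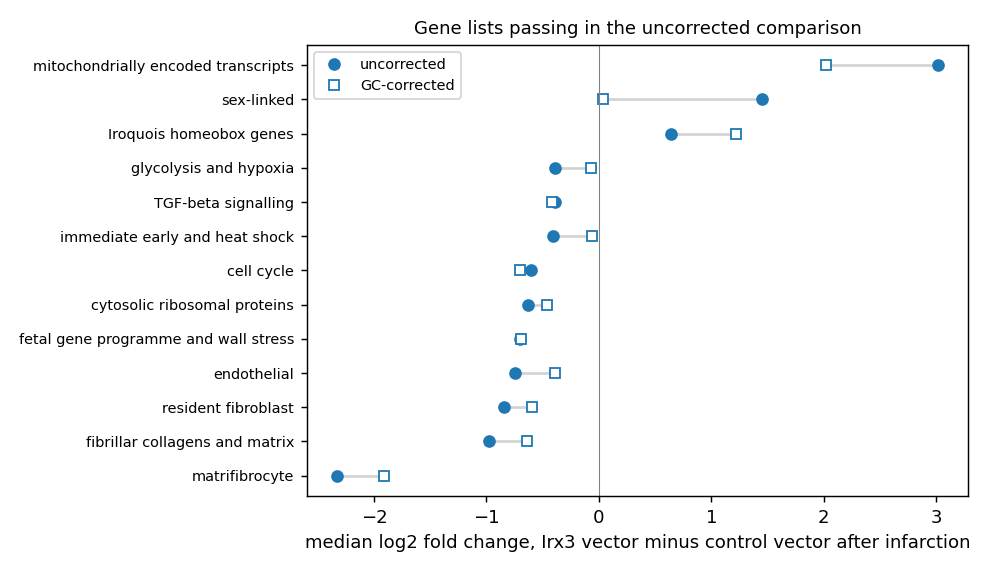
Median log2 fold change of the 13 gene lists that passed for Irx3 vector against control vector after infarction, uncorrected and GC-corrected. The mitochondrially encoded list stood at 3.02 and 2.02, the matrifibrocyte list at -2.33 and -1.91, and the sex-linked list at 1.45 and 0.04.

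The cytokine and interferon lists gave no call in this comparison, uncorrected or GC-corrected. Of 42 cytokine and chemokine genes 11 rose and 5 fell, the same adjusted over the list alone (median 0.45, camera adjusted p = 0.364), the chemokine gene Ccl7 being higher by 2.79 (SE 0.53, GC-corrected 2.04). Of 43 interferon response genes 8 rose and 7 fell, the same adjusted over the list alone (median 0.17 and mean 0.12, though camera's direction was lower, adjusted p = 0.695), with Ifitm3, an antiviral membrane protein gene, at -1.22 (SE 0.25, GC-corrected -0.97). GC-corrected, none of the interferon genes rose and 4 fell (median -0.17), and 6 of the cytokine genes rose and 2 fell (median 0.13). Camera gave no call for the excitation and conduction lists uncorrected, and fry called the conduction list higher (adjusted p = 0.0319). Of 33 genes for calcium handling and excitation 11 rose and 2 fell, the same adjusted over the list alone (median 0.36, camera adjusted p = 0.119), and GC-corrected 8 rose and 3 fell (median 0.23, camera adjusted p = 0.0507). The potassium channel genes Kcnd3 and Kcnj5 rose by 1.65 (SE 0.22, GC-corrected 1.66) and 1.37 (SE 0.20, GC-corrected 1.48). The 23 genes of conduction and gap junctions had 7 rises and 1 fall, the same adjusted over the list alone (camera adjusted p = 0.188). GC-corrected, this list passed (median 0.40, camera adjusted p = 0.00735, and adjusted p = 0.494 with an estimated correlation). The T-type calcium channel genes Cacna1h and Cacna1g rose by 1.86 (SE 0.23, GC-corrected 2.51) and 1.22 (SE 0.15, GC-corrected 1.84). Gja1, the main ventricular gap junction gene, was higher by 1.21 (SE 0.18), a call that ended GC-corrected (0.40, adjusted p = 0.175).

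Among the 8 largest falls with Irx3 vector, Zbtb16, a transcription factor gene that glucocorticoids are known to induce, fell from 220 ± 32.1 to 17.3 ± 3.39 CPM (log2 fold change -3.67, SE 0.18, edgeR adjusted p = 2.93e-07, GC-corrected -3.29). Ddit4, an inhibitor of mTOR signalling, fell by 3.49 (SE 0.21, GC-corrected -2.86) and the kinase gene Map3k6 by 3.52 (SE 0.26, GC-corrected -2.85). The metallothionein gene Mt1 fell by 2.60 (SE 0.21, GC-corrected -2.27) and Pdk4, which restrains glucose oxidation, by 2.53 (SE 0.39, GC-corrected -2.95). Fam107a stood at -4.61 (SE 0.32, GC-corrected -4.54) and Angptl7 at -5.72 (SE 0.64, GC-corrected -5.60), or -6.37 without replicate 3 with Irx3 vector. The clock genes Per1 and Per2 fell by 2.29 (SE 0.23, GC-corrected -1.64) and 3.26 (SE 0.30, GC-corrected -2.82).

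In total, edgeR called 7760 of 15742 genes between the infarcted groups, 3965 higher and 3795 lower with Irx3 vector, and 13 of 47 lists passed. GC-corrected, 4170 of 15182 genes were called, 2177 higher and 1993 lower. Of the 7528 uncorrected calls with a known GC content, 2946 were called in the same direction, 101 in the opposite one and 4481 no longer passed, while 1123 others were gained. Genes of glycolysis and hypoxia fell in 12 of 36 cases and rose in 3, the same adjusted over the list alone (median -0.39, camera adjusted p = 0.00846, and adjusted p = 0.568 with an estimated correlation). Immediate early and heat shock genes fell in 10 of 30 cases and rose in 4, the same adjusted over the list alone (median -0.41, camera adjusted p = 0.0303, and adjusted p = 0.677 with an estimated correlation). Neither list passed GC-corrected (medians -0.07 and -0.06, adjusted p = 0.0698 and 0.422). The immediate early list also lost its call without replicate 3 of infarction with control vector (median -0.30, adjusted p = 0.0701) or replicate 3 with Irx3 vector (median -0.29, adjusted p = 0.0746). The 4 sex-linked genes all rose, the same adjusted over the list alone (median 1.45, camera adjusted p = 0.00188, and adjusted p = 0.552 with an estimated correlation), with Eif2s3y at 1.58 and Ddx3y at 1.32. GC-corrected these stood at 0.18 (adjusted p = 0.219) and -0.10 (adjusted p = 0.471), the list at 0.04 (adjusted p = 0.94). The list of 5 Iroquois genes passed with 2 higher, the same adjusted over the list alone, but it holds Irx3 itself. Its median was 0.64 (camera adjusted p = 0.0302, and adjusted p = 0.552 with an estimated correlation), and 1.22 GC-corrected. It lost its call without replicate 4 with Irx3 vector (median -0.08, adjusted p = 0.0776) or replicate 2 of infarction with control vector (median 0.85, adjusted p = 0.0571), and its median was 0.98 without replicate 1 with Irx3 vector.

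The third comparison set Irx3 vector with infarction against sham, groups that differ in both surgery and vector. Of 40 matrix genes 38 were higher and none lower, with Postn at 6.09 (SE 0.45). The matrix list had 38 higher and 1 lower adjusted over the list alone and a median log2 fold change of 3.23 (camera adjusted p = 3.26e-12, and adjusted p = 0.552 with an estimated correlation). Of 42 cytokine and chemokine genes 38 were higher and none lower, the same adjusted over the list alone (median 3.01, or 3.70 without sham replicate 2, camera adjusted p = 3.63e-09, and adjusted p = 0.552 with an estimated correlation). Of 43 interferon response genes 40 were higher and none lower, the same adjusted over the list alone, with Irf7 at 3.21 (SE 0.29). The interferon list had a median of 2.77 (camera adjusted p = 5.03e-13, and adjusted p = 0.552 with an estimated correlation). Among metabolic genes, 58 of 79 nuclear genes of oxidative phosphorylation and 35 of 42 genes of fatty acid oxidation were lower and none higher. These were 60 and 36 adjusted over the list alone, at medians of -1.09 and -1.41. Camera gave adjusted p = 4.79e-11 and 5.08e-11, and adjusted p = 0.677 and 0.552 with an estimated correlation. Slc27a1, a fatty acid transporter gene, fell by 2.10 (SE 0.19) and Ryr2 by 1.95 (SE 0.27). Mitochondrially encoded genes did not pass as a list against sham, with 8 of 13 higher and none lower, the same adjusted over the list alone. Their median was 1.54 (camera adjusted p = 0.114), and 0.43 GC-corrected. The 24 genes of the fetal programme had 12 higher and 2 lower, the same adjusted over the list alone, and did not pass with camera (median 0.92, adjusted p = 0.0718), though they passed with fry (adjusted p = 0.000992) and GC-corrected (median 1.08, camera adjusted p = 0.0114, and adjusted p = 0.494 with an estimated correlation).

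Among the largest differences from sham, Spp1, which encodes osteopontin, was higher by a log2 fold change of 8.50 (SE 1.73, edgeR adjusted p = 0.000973), and by 5.31 without replicate 1 with Irx3 vector. The macrophage elastase gene Mmp12 was higher by 7.95 (SE 1.46), and by 5.95 without that library. Without sham replicate 2 they were higher by 12.05 and 10.46. The remaining sham libraries held at most 0.0702 CPM of either gene, so these values rest on almost no counts. Cemip, a hyaluronan-degrading protein gene, had 0 sham counts and was at least 220-fold higher, at a floor of 3 counts over the group, and at least 88.5-fold higher without replicate 1 with Irx3 vector. Ucp3, a mitochondrial carrier gene of muscle, went from 280 ± 44.2 to 10.9 ± 7.17 CPM, a log2 fold change of -4.70 (SE 0.57). Lrrc52 and Cdh22 stood at -5.03 (SE 0.50) and -4.42 (SE 0.38). After infarction with control vector Ucp3 held 22.4 to 111 CPM, Lrrc52 0.982 to 4.57 and Cdh22 2.81 to 8.42. With Irx3 vector they held 4.39 to 19.5, 0.109 to 0.912 and 0.296 to 0.926 CPM, further from sham. Spp1 overlapped, at 7.68 to 32.6 CPM with control vector and 2.74 to 475 with Irx3 vector. In all, 9904 of 15742 genes were called, 5545 higher and 4359 lower, and 22 of 47 lists passed. GC-corrected, 8259 were called, and of the 9612 uncorrected calls with a known GC content 6469 kept their direction and 81 turned. Among the Iroquois genes other than Irx3, Irx1 stood at -1.95 (SE 0.48, adjusted p = 0.00316), and at -2.60 without replicate 4 with Irx3 vector. Irx4 at 0.41 (adjusted p = 0.153) and Irx5 at 0.59 (adjusted p = 0.141) passed only GC-corrected (0.99, adjusted p = 0.00719, and 1.19, adjusted p = 0.00556), and Irx5 also without sham replicate 2 (0.99, adjusted p = 0.016).

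The last comparison asked which genes infarction and Irx3 vector changed in opposite directions. Such a call does not require a level nearer sham. With Irx3 vector mt-Nd4l held 197 to 445 CPM, above its sham range of 11.1 to 89.4 CPM. Ky, at 12.6 to 24.4 CPM, spanned its sham range of 14.8 to 19.9 CPM. In the opposite direction to infarction edgeR called 2322 genes, 1365 up and then down and 957 down and then up, while 1114 were called in the same direction in both. Independent calls of the same numbers would give 998.3 and 886.8. GC-corrected, 1597 genes were called opposite, and without replicate 4 of both infarcted groups 1478, or 977 GC-corrected. Angptl7 went from 12.2 ± 3.94 in sham to 1300 ± 806 after infarction and 24.6 ± 19.6 CPM with Irx3 vector, with log2 fold changes of 6.73 and -5.72. Also up and then down were the serine protease gene St14 at 4.69 and -3.58 (GC-corrected -3.76), Cilp2 at 8.04 and -3.45, and Comp at 10.53 and -3.41. Atp2a1, the calcium pump gene of fast skeletal muscle, was the fifth at 5.08 and -5.53, both resting on replicate 1 of infarction with control vector: without it they were 0.60 (adjusted p = 0.49) and -1.09 (adjusted p = 0.214). Down and then up were Ky, a muscle maintenance gene, at -2.52 and 2.63 (GC-corrected 3.07) and the orphan receptor gene Gpr22 at -2.63 and 3.97 (GC-corrected 2.60). So were Lingo3 at -2.85 and 2.86 (GC-corrected 3.43), Gal3st3 at -2.52 and 2.47 (GC-corrected 3.07) and mt-Nd4l at -2.69 and 5.49 (GC-corrected 4.70). The infarction value of mt-Nd4l was -4.13 without replicate 2 of infarction with control vector and -2.18 (adjusted p = 0.0548) without sham replicate 1, and its call also ended without the filter on low counts (adjusted p = 0.0865). It ended as well without replicate 4 of both infarcted groups (-2.30, adjusted p = 0.0829, and GC-corrected -2.33, adjusted p = 0.051). Without replicate 2 of infarction with control vector, Gpr22 stood at -3.33 and 4.60, Lingo3 at -3.50 and 3.45, and the Irx3 vector value of mt-Nd4l at 6.86. Both contrasts use the same control vector infarction libraries, which alone makes them tend to opposite signs. The Pearson correlation across genes was -0.26, against -0.49 in 20 simulations of groups without differences. The covariance of the log2 fold changes was -0.321 and its simulated value -0.0489. With those libraries divided, a pair for each contrast, 1093 to 1637 genes were called opposite, and GC-corrected 516 to 1207. Independent calls of the numbers in each division would give 876.9 to 1285, and GC-corrected 387.5 to 721.2. With replicates 2 and 4 in the infarction contrast 1093 were called against 1129 so expected, and with replicates 3 and 4 there 1234 against 1229, so these divisions showed no excess. GC-corrected they gave 561 against 463.5 and 516 against 486.9. The correlations over the divisions ran from -0.28 to -0.08, and GC-corrected from -0.33 to -0.04.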

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

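The search for libraries far from their group was planned, and of the tests below those of a library batch, of GC content in the mitochondrial rise, of mitochondrial tRNA genes and of the cardiomyocyte share were chosen only after the result was seen. In 428 groups of 4 libraries, 47 had 1 library whose gap to the nearest other, over the whole range, passed Dixon's 95% value, or 11%, while chance flags about 1 in 20 groups. Genes and lists share members and libraries, so these groups are not independent. The share was 10.6% for list scores and 11.9% for genes, and for the 18 groups of library measures such as the total count it was 0. Sham replicate 2 held 13 of them and replicate 4 of infarction with control vector 9.

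Sham replicate 2 had higher list scores than the other 3 sham libraries for matrix (0.39), proteases and inhibitors (0.53), cytokines (0.83), conduction (0.33), resident fibroblast (0.24) and macrophage genes (0.42). Its CPM values stood apart for Comp (3.08), Nppa (97.5), Irx5 (8.16), Gja1 (187), Spp1 (1.26), Mmp12 (0.565) and Cdh22 (17.4), all above the others. Sham replicate 3 was above the others for Rgcc (84.2) and Slc27a1 (737), and sham replicate 4 was above them for Fmod (2.09) and below them for Irx3 (20.5).

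Replicate 4 of infarction with control vector was above the other 3 for the scores of cytokines (3.56), NF-kappaB and inflammasome (2.01) and macrophage genes (3.04), and below them for glycolysis and hypoxia (-0.45). It was above them for Ighg2b (43.9 CPM), Ecrg4 (74.1), Col6a5 (37.8), Chad (41.2) and Cytl1 (30.1). Replicate 1 of that group was above for the skeletal muscle genes Myh2 (79.1) and Atp2a1 (182), and the infarction log2 fold change of Myh2 was 7.77 with that library and 0.36 (adjusted p = 0.833) without it. Replicate 2 was above for Acsm5 (3.60), mt-Tl2 (1.10), mt-Atp8 (1.46) and mt-Tw (1.46) and below for Mcm2 (19.9), and replicate 3 was below for Cacna1h (9.17).

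With Irx3 vector, replicate 1 was below the others for the endothelial score (-0.86) and for mt-Tw (5.82), and above for the adipocyte score (3.36), C1qtnf3 (26.8), Chad (3.21), Cytl1 (2.86), Spp1 (475) and Mmp12 (139). Replicate 3 was below for immediate early genes (0.05) and above for Schwann and neuronal genes (0.08). Replicate 4 was below for the atrial score (0.68) and above for Clcn1 (5.85) and mt-Atp8 (32.4).

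Fold changes with Irx3 vector that followed GC content were the first pattern weighed. With mitochondrially encoded genes removed, the correlation of fold change and GC content was still -0.65. That test does not decide whether counts taken up by mitochondrial transcripts made the trend. Such a loss scales all other genes alike, so removing these few genes could hardly move a correlation across genes. A change in cell composition was argued against as the whole cause by the slope per 10 points of GC. It was -0.71 (SE 0.12) within 20 cell type lists, against -0.88 (SE 0.0097) over all genes. These errors are over genes and not over mice, so they do not exclude it. A shift in how transcripts of different GC content were recovered stays a candidate explanation: within the nuclear genes of oxidative phosphorylation, which share a function, the slope was -0.66 (SE 0.10). It cannot be told apart from a library batch that follows the vector group, because the labels give 1 batch for all libraries, and the 4 Irx3 vector libraries lay 0.5 below the lowest other library in their correlation with GC content, nor from an effect of the vector itself on such transcripts.

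The rise of mitochondrially encoded transcripts with Irx3 vector was the second. GC content as the whole cause was argued against, since the median was 3.02 before and 2.02 (SE 0.47) after correction. It was lower, at 1.15 (SE 0.45), without replicate 4 of both infarcted groups as well. These errors are over genes and not over mice. The correction follows the trend of all genes, so a GC effect particular to mitochondrial transcripts is not excluded. A higher share of cardiomyocytes was argued against, since the nuclear genes of oxidative phosphorylation had a GC-corrected median of 0.03 (SE 0.07). That is a transcript level and not a count of cells, so a changed share of cells is not excluded. A larger carry-over of RNA without a poly(A) tail over the whole library was argued against by the share of counts in small nuclear, nucleolar and ribosomal RNA genes, at 0.699 (SE 0.14) of its level with control vector. But all 16 tested mitochondrial tRNA genes were called higher, 13 of them GC-corrected, and mt-Nd6 rose by 5.17 against 2.38 for mt-Nd4, so a carry-over of mitochondrial RNA alone stays open. A library difference of another kind and an effect of Irx3 vector on mitochondria stay open too, and no value here separates them.

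Lower levels of glucocorticoid-inducible genes with Irx3 vector were the third. Of 22 such genes 20 were lower and none higher GC-corrected, at a median of -1.7 (SE 0.27). The values of 11 had been seen before the genes were listed, so only the other 11 are a test. Those 11 unseen genes had a GC-corrected median of -0.92 (SE 0.37), 9 lower and none higher. This argued against GC content as the whole cause. A lower glucocorticoid signal at collection is a candidate explanation, since the unseen genes were lower too. A different time of day at collection stays open. The clock genes Arntl and Npas2 stood at 2.34 (SE 0.30) and 2.33 (SE 0.31) GC-corrected, and their mean differed by 2.46 (SE 0.26) from that of Dbp, Nr1d1 and Nr1d2. That difference passed the size set in advance for a shift in time. Dbp, Nr1d1 and Nr1d2, which such a shift should move the other way, stood at -0.12 (SE 0.36), 0.57 (SE 0.24) and -0.81 (SE 0.15). These genes alone did not show a shift of both arms. Per1 and Per2 were lower as well, Per1 at -1.64 (SE 0.2) GC-corrected, but Per1 is also 1 of the 22 inducible genes. Of the 18 listed clock genes, 4 were higher and 10 lower GC-corrected. The hours of collection are not given in the sources used here, and an effect of Irx3 vector on these genes stays open as well.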

How the results depend on the processing

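The GC correction and the setting without replicate 4 of both infarcted groups were chosen after seeing the data, and the other alternatives were planned. Counts of called genes stayed within 1.5 times in all 4 comparisons under RLE factors, upper-quartile factors, the DESeq2 test and other filters. They also did with only the 2 groups compared and with mitochondrial genes removed. A required fold change above 1.5 lowered the calls to 3689 after infarction, 2787 with Irx3 vector, 5535 against sham and 477 opposite, by construction. With Irx3 vector 4170 genes were called GC-corrected and 3936 without both libraries as well, and the trend this removes was measured. Opposite genes numbered 1478 without both libraries, 977 with the GC correction too, and 1493, 1222, 1516, 1093 and 1234 in 5 of 6 divisions of the shared libraries, where fewer libraries enter each contrast. Lists passing fell to 0 in each comparison with an estimated correlation and rose to 20 with Irx3 vector under the GC correction without both libraries; the cause was not tested. With 1 library left out, calls were 6708 to 8513 after infarction, 6765 to 8353 with Irx3 vector, 9007 to 10586 against sham and 1627 to 3412 opposite, lists passing 27 to 29, 13 to 19 and 22 to 26, and Irx3 3.95 to 4.26. A replicate block gave 6624, 6679, 9077 and 1666 genes and Irx3 at 4.11. Numbers did not pair libraries: residual correlations of the same number were -0.42 to 0.10. Called values that turned were Ddx3y with Irx3 vector, -0.10 GC-corrected and -0.17 without both libraries too, and the sex-linked list, whose test changed sign at a median of 0.01; the Iroquois list median was -0.08 without replicate 4 with Irx3 vector; the cause was not tested. Values of Irx1, Irx2, Irx3 and Irx5 that passed no test also changed sign under some settings, with Irx3 vector Irx2 to -0.17 and Irx5 to -0.08 without that library. GC-corrected, 52 of 55 named genes with Irx3 vector kept direction and call, as did 49 of 49 after infarction and 24 of 26 against sham, where 2 were gained. Without a filter 5 of 50 named infarction genes lost their call. For lists, leaving out 1 library kept 335 of 336 tests after infarction, 152 of 156 with Irx3 vector and 264 of 264 against sham. In simulated data with 4 libraries per group most 1.5-fold changes went undetected.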

Other observations

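Of the tests in this part, the one on GC-corrected calls was chosen only after the result was seen. Several groups of genes not described so far moved after infarction under control vector. Complement genes rose in 20 of 22 cases and fell in 1 (20 and 1 adjusted over the list alone; median log2 fold change 2.46; camera adjusted p = 3.63e-09, and adjusted p = 0.552 with an estimated correlation). Genes of NF-kappaB signalling and the inflammasome, an innate alarm pathway, rose in 27 of 33 cases (28 adjusted over the list alone; median 1.55; camera adjusted p = 1.24e-08, and adjusted p = 0.552 with an estimated correlation). Proteases of the matrix and their inhibitors rose in 20 of 29 cases and fell in 2 (22 and 2 adjusted over the list alone; median 2.47), and genes of TGF-beta signalling rose in 22 of 32 and fell in 2 (22 and 2 adjusted over the list alone; median 1.05), with camera adjusted p = 2.94e-07 and 4.71e-08, and adjusted p = 0.552 for both with an estimated correlation. Markers of epicardium and mesothelium rose in 10 of 12 cases (10 adjusted over the list alone; median 3.67, and 2.34 without replicate 4 of infarction with control vector; camera adjusted p = 0.00064, and adjusted p = 0.552 with an estimated correlation). Dendritic cell markers rose in 7 of 9 cases, and B and plasma cell markers rose in 7 and fell in 1 of 9 (7, and 8 with 1, adjusted over the list alone), with camera adjusted p = 0.0125 and 0.0136, and adjusted p = 0.552 for both with an estimated correlation. The B and plasma cell call ended under the stricter filter on low counts (adjusted p = 0.0606).

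Cytosolic ribosomal protein genes rose in 17 of 46 cases after infarction and fell in 1 (16 and 1 adjusted over the list alone; median 0.32; camera adjusted p = 0.00618, and adjusted p = 0.735 with an estimated correlation), the opposite direction to their change with Irx3 vector. Genes of glycolysis and hypoxia went both ways after infarction, with 10 higher and 15 lower of 36 (10 and 15 adjusted over the list alone; camera adjusted p = 0.253), as did angiogenesis genes, with 15 higher and 9 lower of 41 (15 and 10 adjusted over the list alone; median -0.16, mean 0.24; camera adjusted p = 0.948). Endothelial markers did not pass after infarction (1 higher and 4 lower of 15; 1 and 4 adjusted over the list alone; median -0.25; camera adjusted p = 0.223) and were lower in Irx3 vector hearts than in sham (2 higher and 10 lower; 2 and 10 adjusted over the list alone; median -0.85; camera adjusted p = 0.00107, and adjusted p = 0.552 with an estimated correlation; GC-corrected median -0.51). The clock genes did not pass camera with Irx3 vector uncorrected (5 higher and 9 lower of 18; 5 and 9 adjusted over the list alone; camera adjusted p = 0.0718, and fry adjusted p = 0.00215) and passed GC-corrected (4 higher and 10 lower; median -0.65; camera adjusted p = 0.0355, and adjusted p = 0.494 with an estimated correlation). Matrifibrocyte markers of Irx3 vector hearts stayed above sham, with 6 of 9 higher and 1 lower (6 and 1 adjusted over the list alone; median 4.33; camera adjusted p = 0.0285, and adjusted p = 0.709 with an estimated correlation).

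For the gene counts of the 3 contrasts, the real split gave the largest count among all splits of the same libraries. The real splits gave 7662 genes after infarction, 7760 with Irx3 vector and 9904 against sham, and the highest of the other splits gave 1, 0 and 0, so that 1 of 35 splits reached the real count each time. GC-corrected, Irx3 vector gave 4170 genes and the highest other split 61. Every other split mixes the true groups on both sides, so a large real difference adds to the spread within each side and lowers the calls. The low counts of those splits therefore do not measure how many genes chance alone would call. Nor can they bear on a library difference that follows the vector group. For opposite genes the splits decide nothing either: the other splits of the infarcted libraries called 0 genes, so none could be opposite. Of 70 assignments 2 gave as many as the real 2322, the other being the exact mirror with the infarcted groups exchanged, at 5011.

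Chance cannot be excluded for the number of lists that passed. After infarction 28 passed, and 12 of 35 splits gave as many, with a highest other of 31. With Irx3 vector 13 passed, and 30 of 35 splits gave as many, with a highest other of 31. Against sham 22 passed, and 17 of 35 splits gave as many, with a highest other of 30. Splits that exchange 1 library between the groups keep part of the real difference, so their passing lists are not chance alone. After infarction the highest other, 31, was such a split. With Irx3 vector a split with 2 libraries of each group on either side also passed 31. Camera at its preset correlation thus passed as many lists in other groupings of the same libraries. A camera p does not by itself show that a list moved.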
